A study of Mus musculus with 2 samples.

How the data were processed

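Single-cell RNA was measured in 2 droplet libraries (10x Genomics), 1 per group. One came from tumours grown from 4T1 cells carrying a control guide RNA, the other from tumours grown from 4T1 cells in which Kindlin-2 had been knocked out. The 4T1 line is a mouse mammary carcinoma line used as a model of triple-negative breast cancer. Per the labels, the cells were injected into the mammary fat pads of female BALB/c mice and the tumours were excised at 150 mm3. They were digested for 45 min, and live cells were sorted by whether they carried the mCherry signal. The labels do not say which sorted fraction was loaded, in what proportion, or how many tumours were pooled.

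The deposited matrix holds UMI counts, that is, whole-number counts of distinct RNA molecules per gene and cell barcode, for 32285 genes and 15288 barcodes. The authors' processing notes name Cell Ranger 2.1.1 and the mm10 genome, while the matrix header names Cell Ranger 6.0.1, so the version that produced the deposited counts is uncertain. All values are whole numbers. Cell calling had been applied before deposit, and the labels do not say how, nor whether reads were subsampled to equal depth when the libraries were joined. The deposited barcodes hold no other measurement, and their suffix marks the library. Suffix 1 was taken as the control library and suffix 2 as the knockout library because the labels number the libraries in this order. That match rests on the number alone.

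Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 and removed (226 of 7747 control cells, 2.92%, and 224 of 6962 knockout cells, 3.22%). Counts were scaled per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 neighbours was divided into clusters by the Leiden method at resolution 1.0 (igraph 0.11.9), without integration of the libraries. A cluster was called by a cell type with the ending "-like" only from markers fixed before the data were examined. The scoring rule that applied the markers was set, and once revised, after the clusters had been seen. A list each for luminal and basal mammary gland cells was added at that point, and the clusters they marked were left unnamed. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

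UMIs were summed per library and cell class and scaled by the class total on the usual CPM scale, and groups were compared as the log2 ratio of CPM, knockout over control. Intervals are exact 95% intervals: Clopper-Pearson for shares of cells, Poisson for CPM, and conditional binomial for ratios. With 1 library per group there is no residual error between samples, so no test, p-value or count of changed genes is given. Intervals cover counting error only and not differences between tumours. They are too narrow where 1 cell holds much of a gene's UMIs, and the text gives that percentage. A gene with no UMI in 1 library is given as a bound against 3 counts over that library and class.

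Genes were named by rules fixed before the data were examined. In each class with at least 100 cells in both libraries, the 10 genes higher and the 10 lower with the interval bound farthest from 0 were ranked, among genes with at least 50 UMIs and a 2-fold difference. Markers of other classes and immunoglobulin, T cell receptor, haemoglobin, mitochondrial and ribosomal protein genes were left out, as were Xist and Y-linked genes. The text also names Fermt2, a fixed set of immune and tumour genes, and members of fixed gene lists. Those with the highest and lowest ratios were to be named, and further members were picked after the values were seen. A list is described by the median log2 ratio of its members with at least 20 UMIs, by how many were at least 1.5-fold higher or lower, and by its percentile among 10000 random lists matched on expression. The percentile is a description, because genes are not independent replicates. Shares of cells with a UMI were also computed after thinning each cell to 500 UMIs (T cells) or 1000 UMIs (tumour cells), beside the share in a class that should lack the gene. Gene positions came from a GENCODE annotation of mm10, which held 99.8% of the matrix's gene identifiers.

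The control library held 214163620 UMIs and the knockout library 180774106. Ratios were tested on simulated Poisson counts with known changes, drawn per class without differences between cells or between tumours. The interval rests on the same model, so this checks the calculation and not the error rate in real data. The interval excluded 0 for 97.0% of 2-fold and 90.9% of 1.5-fold simulated changes in tumour cells, and for 88.5% and 53.8% in NK cells. Among unchanged genes it did so for 4.82% in tumour cells and 4.24% in NK cells. Alternatives fixed before the data were examined were other cell filters, cluster resolutions, scalings, gene minimums and depths, doublets kept, and cells weighted equally. Added afterwards were list medians within clusters, the CD8-marked T cell cluster alone, the monocyte-like cells counted with the macrophages, and the alternatives for the shares of small classes. No list or gene was compared in classes with under 100 cells in either library, except Fermt2.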

Results

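The series concerns Kindlin-2 in the immune evasion of breast cancer. Kindlin-2, encoded by Fermt2, is an adaptor protein that binds integrin tails and activates integrins together with talin. The data are 2 single-cell RNA libraries from 4T1 mammary tumours in mice, 1 from a control guide RNA and 1 from the Kindlin-2 knockout, with no replicates. The control library held 8038 barcodes with a median of 21758.5 UMIs and 4661.5 genes, and the knockout library held 7250 with medians of 15287 UMIs and 3872 genes. After filtering and removal of called doublets, 7521 control and 6738 knockout cells were analysed. Every difference below is between these libraries, and its interval covers counting error only.

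Fermt2 RNA was lower in the tumour cells of the knockout library. In tumour epithelial-like cells it stood at 40.6 CPM (95% interval 39.7 to 41.7) in the control and 13.7 CPM (13.005 to 14.4) in the knockout, a log2 ratio of -1.57 (-1.65 to -1.49), or 2.97-fold lower. A Fermt2 UMI was found in 64.6% of control and 37.4% of knockout tumour cells, at median depths of 35924.5 and 40796.5 UMIs. With each cell thinned to 1000 UMIs the shares were 3.64% and 1.54%. In T cell-like cells, which should lack the gene, the shares were 0.808% and 0.401% at median depths of 6182 and 6499 UMIs, and 0.164% and 0% thinned, the latter allowing up to 0.378%. Host cells that express Fermt2 were nearer to each other between the libraries: fibroblast-like cells had 429 and 295 CPM (log2 ratio -0.54, interval -0.65 to -0.43), and endothelial-like cells 280 and 296 CPM (0.08, -0.23 to 0.38). The ratio lay between -1.37 and -1.85 in each of the 5 tumour clusters. Fermt2 (ENSMUSG00000037712) lies on the minus strand of chromosome 14 at 45458795 to 45530118 in mm10. A guide need not lower the RNA of its target, so the level shows how the libraries differ and not how much protein remained.

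The first comparison asks how the cell make-up of the tumours differed. NK cell-like, plasmacytoid dendritic-like, monocyte-like, conventional dendritic-like and T cell-like cells took larger shares in the knockout library. NK cell-like cells, innate lymphocytes that kill tumour cells, made up 1.81% of control and 7.38% of knockout cells, a log2 ratio of 2.03 (1.75 to 2.31), or 4.08-fold. T cell-like cells made up 8.23% and 14.8% (0.85, 0.70 to 0.99), monocyte-like cells 3.70% and 9.45% (1.35, 1.15 to 1.56), and conventional dendritic-like cells 1.98% and 4.94% (1.32, 1.04 to 1.61). Plasmacytoid dendritic-like cells, specialised producers of type I interferon, were 0.399% and 1.75% (2.13, 1.55 to 2.76). Tumour epithelial-like cells made up 50.9% of control and 34.8% of knockout cells (-0.55, -0.62 to -0.47), macrophage-like cells 20.04% and 15.4% (-0.38, -0.50 to -0.27), and neutrophil-like cells 7.42% and 4.02% (-0.88, -1.10 to -0.67). The macrophage ratio depends on the monocyte-like cluster 7, which was named by its leading genes although its macrophage score was higher (4.304 against 3.18 for monocytes): macrophage-like and monocyte-like cells together made up 23.7% and 24.8% (0.066, -0.031 to 0.16).

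Among immune cells alone, 3321 in the control and 3944 in the knockout, the shifts went the same ways. NK cell-like cells were 4.10% and 12.6% of immune cells (1.62, 1.35 to 1.91), and T and NK cell-like cells together 22.7% and 37.9%. Neutrophil-like cells were 16.8% and 6.87% (-1.29, -1.505 to -1.08), macrophage-like cells 45.4% and 26.3% (-0.79, -0.90 to -0.67), and monocyte-like cells 8.37% and 16.2% (0.95, 0.74 to 1.16), with the macrophage-like and monocyte-like cells together at 53.7% and 42.4% (-0.34, -0.44 to -0.24). Fibroblast-like cells were 1.45% and 1.499% of all cells, a ratio whose interval (-0.36 to 0.45) includes 0. The same holds for mast or basophil-like cells (0.346% and 0.371%; 0.529% and 1.17% with the stricter cell filter, which named a further cluster), B cell-like cells (0.239% and 0.416%) and pericyte or smooth muscle-like cells (0.226% and 0.134%). Endothelial-like cells were 0.691% and 0.430% (-0.68, -1.39 to -0.00), a ratio that turned to 0.20 with coarser clusters. Unnamed clusters held 2.58% of control and 4.56% of knockout cells, among them luminal and basal mammary gland cells led by Wfdc18 and Krt5. Live cells had been sorted on mCherry in unstated proportions, so the sort can set the share of tumour cells and all shares that include them.

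**Figure D1:**
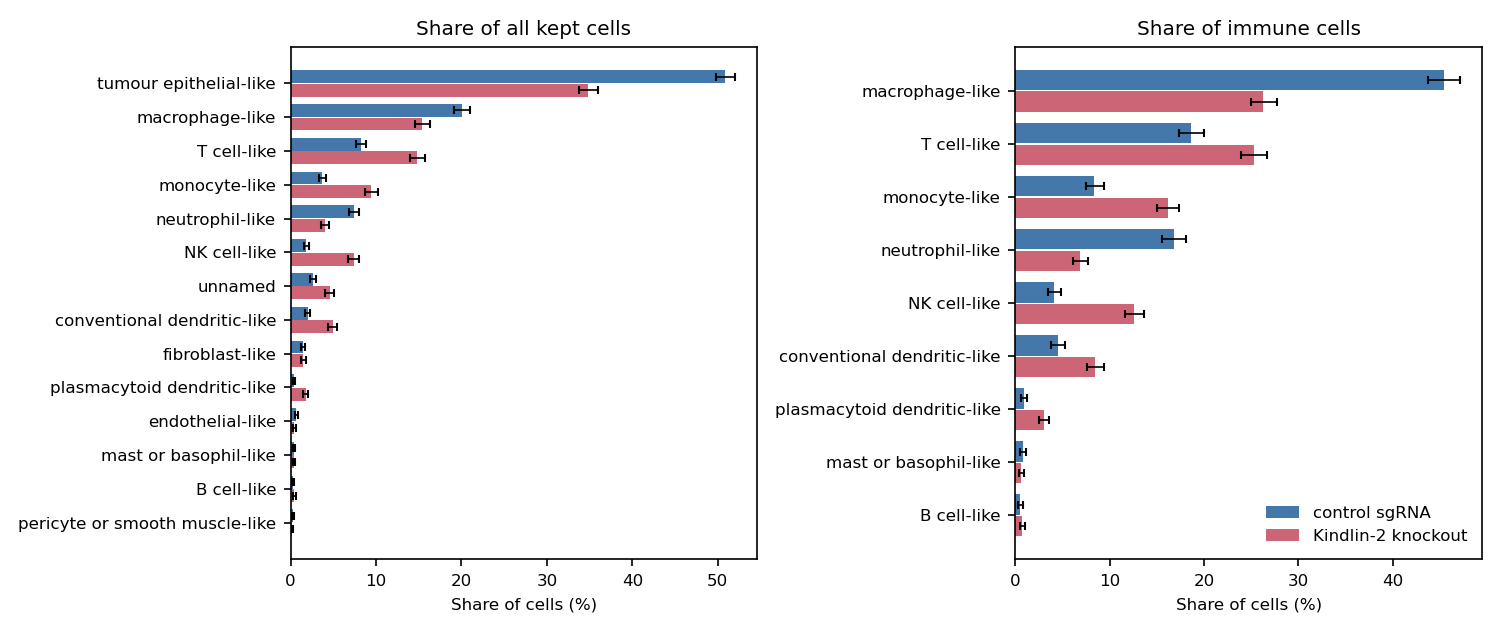
Percent of all kept cells (left) and of immune cells alone (right) in each cell class, for the control library (blue) and the knockout library (red), with exact 95% binomial intervals. NK cell-like cells go from 4.10% to 12.6% of immune cells and neutrophil-like cells from 16.8% to 6.87%.

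Within the tumour cells, genes of the interferon response were higher in the knockout library. Of 36 measured members, 19 were at least 1.5-fold higher and 0 lower, with a list median log2 ratio of 0.69 (percentile 100 among random lists). Ifit3, an antiviral interferon-induced gene, stood at 11.8 and 38.1 CPM (1.69, 1.61 to 1.77), and the guanylate-binding protein genes Gbp5, Gbp3 and Gbp2 at 8.06 and 20.2, 33.1 and 75.2, and 113 and 240 CPM. Cd274, which encodes the checkpoint ligand PD-L1, was at 18.6 and 55.1 CPM (1.56, 1.499 to 1.63), and Ido1, which degrades tryptophan, at 4.72 and 11.4 CPM. The T cell-attracting chemokine gene Cxcl9 was at 21.0 and 18.8 CPM, and Irf1 at 359 and 338 CPM. The tumour cells fell into clusters led by different genes: clusters 2 (Ibsp, Csf3, Cxcl1) and 3 (Lcn2, H19, Slpi) held most control cells, and clusters 0 (Ifit3, Hells, Mcm6), 5 (Ghr, Nhs, Pdgfc) and 6 (Cenpf, Top2a) most knockout cells. Compared cluster by cluster, the interferon median was above 0 in all 5, from 0.23 to 0.81, and averaged 0.46.

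Genes of antigen presentation by MHC class I differed in both directions, all but 1 of 21 by less than 1.5-fold. The list median was 0.21 (percentile 99.2), with 1 of 21 members at least 1.5-fold higher and 0 lower. The peptide-loading and processing genes Tapbpl (23.04 and 35.9 CPM), Psmb10 (325 and 486 CPM) and Tap1 (71.4 and 97.6 CPM) were higher in the knockout, as was the non-classical H2-T23 (141 and 199 CPM). B2m, the invariant light chain of class I molecules, was at 2275 and 1703 CPM (-0.42, -0.43 to -0.41), H2-D1 at 4051 and 3317 CPM (-0.29), and H2-K1 at 1731 and 1508 CPM (-0.20), each less than 1.5-fold lower. The list median was above 0 in all 5 clusters, from 0.046 to 0.36.

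Genes of chemokines and growth factors differed in both directions in the tumour cells. Ccl2, which draws monocytes, was at 72.1 and 3.31 CPM (-4.44, -4.60 to -4.30). Csf3, the growth factor of neutrophils, was at 138 and 50.3 CPM (-1.45), the neutrophil chemokine genes Cxcl1 and Cxcl2 at 472 and 177 (-1.42) and at 29.4 and 7.98 CPM, Il1a at 41.1 and 8.52 CPM (-2.27), and the macrophage growth factor Csf1 at 88.1 and 64.5 CPM (-0.45). The list members with the highest ratios were Ccl22, Cxcl12 and Ccl12, all under 2 CPM (Ccl12 at 0.568 and 1.57 CPM), and Il33 (4.95 and 11.9 CPM). Over the chemokine and growth factor list, 13 of 45 members were at least 1.5-fold higher and 14 lower, with a median of -0.13 (percentile 0.05). In the 5 clusters taken singly, Ccl2 lay between -3.13 and -6.27, Csf3 between -0.17 and -1.39, Cxcl1 between -0.32 and -1.16, and Cd274 between 0.34 and 1.66. UMIs of neutrophil markers in the tumour cells were also lower, at 139 and 59.3 CPM. Most of both sums was 1 gene, Mmp9, which was also a leading gene of a tumour cluster at resolution 2.0. The sums therefore need not reflect neutrophil RNA. S100a8 was at 8.10 and 2.75 CPM and S100a9 at 12.4 and 3.15 CPM. UMIs of macrophage markers in the tumour cells were at 53.5 and 59.0 CPM. Genes of the cytotoxic list of lymphocytes were higher in these cells (median 0.45; 8 of 21 higher, 2 lower), though by cluster the median ran from -0.51 in cluster 3 to 1.10 in cluster 6, with UMIs of T cell markers at 5.64 and 8.20 CPM and of NK cell markers at 3.23 and 4.51 CPM.

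Genes of adhesion, matrix and TGF-beta signalling included large differences. In the Kindlin and integrin adhesion list the integrin subunit genes Itgb3 (5.50 and 1.23 CPM, -2.16) and Itgb5 (123 and 53.9 CPM, -1.19) were lower with Fermt2, while Tln2, a talin gene, was higher (19.6 and 30.1 CPM) and so was Itgb6 (4.02 and 6.29 CPM). That list had a median of 0.00 (percentile 17.1), with 2 of 28 members higher and 3 lower. TGF-beta signalling had a median of -0.26 (percentile 0), with 0 of 24 higher and 6 lower, among them Tgfbr3 (13.8 and 6.61 CPM), Id2 (23.4 and 12.9 CPM) and Thbs1 (80.0 and 46.7 CPM). The receptor gene Tgfbr2 was at 62.7 and 90.6 CPM, and Tgfb1 itself was at 59.0 and 56.2 CPM. By cluster the TGF-beta median ran from -0.28 in cluster 6 to -0.022 in cluster 2 (3 of 24 higher, 4 lower) and -0.01955 in cluster 0, and averaged -0.15. Extracellular matrix genes had a median of -0.35 (percentile 0; 4 of 29 higher, 9 lower), with the collagen gene Col5a1 at 36.2 and 16.1 CPM and the matrix protease gene Mmp9, also a neutrophil marker, at 112 and 48.5 CPM. Of the YAP and SRF targets, 4 of 21 were higher and 4 lower (median -0.18, percentile 0.29), and Ccn2, a matricellular target of YAP, was at 31.6 and 8.62 CPM.

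Epithelial and mesenchymal genes did not move as blocks. The tight junction genes Cldn7 (49.6 and 1.81 CPM, -4.77) and Cldn3 (165 and 80.1 CPM) were lower and Krt14, a basal keratin, was higher (43.7 and 95.4 CPM), while Cdh1 (117 and 136 CPM) and Epcam (389 and 416 CPM) were close. Cldn7, Krt14, Cdh1 and Epcam were among the markers that named these clusters. The epithelial list had a median of -0.17 (percentile 0.40; 2 of 16 higher, 4 lower) and the mesenchymal list -0.08 (percentile 4.66; 2 of 17 higher, 5 lower). Within clusters the epithelial median ranged from -0.25 in cluster 6 to 0.49 in cluster 2 (7 of 16 higher, 1 lower). Vim was at 3246 and 4182 CPM, and Sparc at 184 and 90.6 CPM.

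Cell cycle genes were higher in knockout tumour cells as a class, but not when averaged over clusters. The list median was 0.35 (percentile 100), with 2 of 26 members at least 1.5-fold higher, Top2a (184 and 299 CPM) and Ccne2 (3.77 and 6.80 CPM), and 0 lower. Mki67, a proliferation marker, was at 77.1 and 106 CPM. A Mki67 UMI was found in 28.0% of control and 40.7% of knockout tumour cells, and in 4.37% and 7.17% with each cell thinned to 1000 UMIs. For Top2a the shares were 48.1% and 67.7%, thinned 9.38% and 14.4%. T cell-like cells also cycle and give no empty background: their thinned Mki67 shares were 6.09% and 4.41%. By cluster the cell cycle median ran from -0.46 in cluster 0 (0 of 26 higher, 9 lower) to 0.46 in cluster 2 (10 of 26 higher, 0 lower). It was -0.40 in cluster 3, -0.14 in cluster 6 and 0.010 in cluster 5, and averaged -0.11, the reverse of the class value. Clusters 0 and 6 are themselves led by genes of dividing cells. Genes of the stress response to dissociation were lower (median -0.42, percentile 0; 0 of 18 higher, 5 lower; -0.28 averaged over clusters), with Btg2 at 160 and 39.2 CPM and the heat shock gene Hspa1b at 163 and 59.5 CPM. Hypoxia and glycolysis genes had a median of -0.15 (percentile 0.11; 1 of 28 higher, 4 lower), led by the angiogenic factor Vegfa at 57.7 and 13.9 CPM (-2.06), and by cluster the list ran from -0.14 to 0.20, while Vegfa stayed between -1.10 and -2.13 in each.

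Ranked by size, the genes highest in knockout relative to control tumour cells included Epdr1, Gm37256, Csn3, Dennd2a, Ube2ql1, Cyp7b1, Adgrl3, Pof1b and Sis. Epdr1 had 370 UMIs in the knockout and none in the control (168-fold higher against 3 control counts, exact log2 bound 7.09). Csn3, a milk casein gene, was at 0.332 and 9.20 CPM, with 18.5% of its UMIs in 1 cell. The genes lowest in the knockout were Pitx1, Rab6b, Gm17268, Cldn7, Nox4, C1qtnf4, Mal2, Ccl2, Grb14 and Gm36696. Pitx1, a homeobox transcription factor gene, had 917 UMIs in the control and none in the knockout (224-fold lower against 3 knockout counts, exact log2 bound -7.51). Rab6b was at 26.3 and 0.558 CPM (-5.56), and Nox4, an NADPH oxidase gene, at 8.27 and 0.244 CPM (-5.08).

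**Figure D2:**
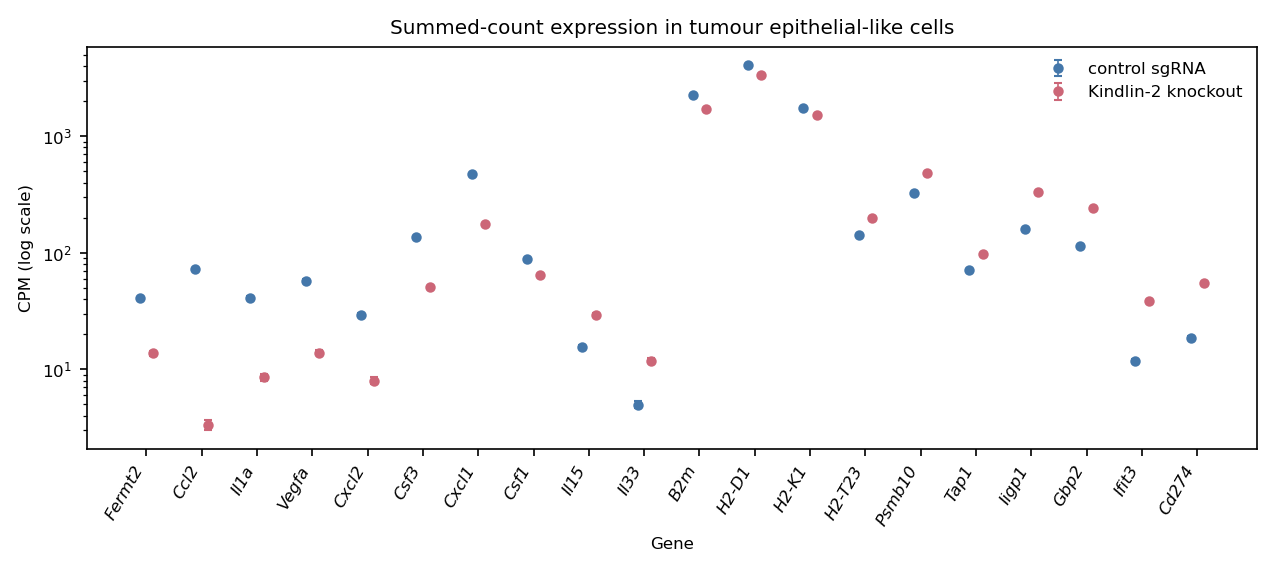
Summed-count CPM on a log scale of 20 fixed or list genes in tumour epithelial-like cells of the control (blue) and knockout (red) library, with exact 95% Poisson intervals, most of them smaller than the points. Ccl2 lies at 72.1 and 3.31 CPM and Cd274 at 18.6 and 55.1 CPM.

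Macrophage-like cells of the knockout library, 1037 against 1507 in the control, had more RNA of interferon and MHC class II genes. The interferon list had a median of 0.57 (percentile 100; 18 of 36 higher, 0 lower), with Rsad2 at 90.9 and 246 CPM (1.44, 1.37 to 1.51), Isg15 at 128 and 291 CPM, and the T cell chemokine gene Cxcl9 at 273 and 558 CPM. The MHC class II list had a median of 0.36 (percentile 100; 2 of 13 higher, 0 lower), with Ciita, the master regulator of these genes, at 44.1 and 77.4 CPM, and H2-Ab1 at 2086 and 3070 CPM. Of the inflammatory macrophage list 4 of 19 members were higher and 0 lower (median 0.22): Ccl5 was at 82.6 and 228 CPM and Cxcl10 at 154 and 254 CPM, whereas Il1b was at 1843 and 1460 CPM. Il12b, also higher, had 80.6% of its UMIs in 1 cell. The alternatively activated list had a median of 0.0066 (percentile 50.6), with 8 of 23 higher and 1, Mmp12 (618 and 401 CPM), lower. Arg1 was at 1596 and 1440 CPM and Mrc1 at 799 and 773 CPM. Cluster 1 (C1qa, Apoe, Arg1, Mmp12) held most of the class in both libraries, and cluster 17 (Ccl8, C1qb), with a median of 1723.5 UMIs, most of the rest, but the mix differed: cluster 1 made up 82.6% and 65.5% of the class and cluster 17 15.9% and 32.3%. In clusters 1 and 17 taken singly the interferon median was 0.56 and 0.57, the MHC class II median 0.37 and 0.67, and the inflammatory median 0.25 and -0.084. Lists of lymphocyte genes were also higher in the class: the cytotoxic list had a median of 0.66 (7 of 12 higher) and the regulatory T cell list 0.54 (4 of 10 higher). By cluster the cytotoxic median was 0.66 in cluster 1 and -0.38 in cluster 17 (2 of 5 higher, 1 lower).

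The ranked macrophage genes included the complement gene C4b (20.9 and 70.0 CPM, 1.75), the lipase gene Lpl (2.80 and 12.5 CPM), Bmp8a and Adgrl3 on the higher side, and Il7r, an interleukin receptor chain (146 and 51.2 CPM, -1.51), Tmeff1 (12.8 and 4.41 CPM) and Tbx3 on the lower side. In 10 of the 20, over 25% of the UMIs sat in 1 cell, as for Mucl1 (100%), Cxcl13 (84.1%) and Ctsk (67.7%). The lower-ranked Ibsp, H19 and Mgp were abundant in control tumour cells, at 289, 96.0 and 264 CPM. Tmeff1 was at 26.3 CPM in control tumour cells and Adgrl3 at 8.71 CPM in knockout tumour cells.

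T cell-like cells numbered 619 in the control and 998 in the knockout, and their make-up differed. Cytotoxic genes were lower in the knockout class as a whole, with a median of -0.66 (percentile 0; 2 of 24 higher, 13 lower). Gzma was at 615 and 87.8 CPM, with 20.8% of its UMIs in 1 cell, Gzmb at 565 and 327 CPM (-0.79, -0.86 to -0.71), and Xcl1, which attracts dendritic cells, at 245 and 104 CPM. Eomes was higher (13.4 and 28.9 CPM), and Ccl5 was higher by less than 1.5-fold (774 and 1066 CPM). Ifng, the main T cell interferon, was close at 239 and 235 CPM. Genes of naive or memory T cells were higher (median 0.67, percentile 100; 6 of 11 higher, 0 lower), with S1pr1, which lets T cells leave tissue, at 60.03 and 150 CPM and the transcription factor gene Tcf7 at 51.8 and 110 CPM. Regulatory T cell genes were higher (median 0.46, percentile 100; 4 of 15 higher, 0 lower), with Foxp3 at 75.3 and 132 CPM (0.81, 0.64 to 0.98), and with every cell weighted equally the median was 0.18. In the exhaustion list (median -0.41, percentile 0; 2 of 17 higher, 5 lower) Pdcd1, the gene of the PD-1 receptor, was at 353 and 196 CPM and Havcr2 at 99.2 and 55.9 CPM, while Tox was at 585 and 976 CPM and Ctla4 at 506 and 742 CPM.

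These class values go with different clusters of T cells. In the control most cells lay in cluster 12 (Cd8a, Cd8b1, Nkg7) and cluster 8 (Themis, Cd28, Icos), and in the knockout in cluster 8 and cluster 10 (Il2ra, Ctla4, Foxp3). The CD8-marked cluster 12 held 191 control and 104 knockout cells, 30.9% and 10.4% of the class. Cluster 8 held 190 and 599 cells and cluster 10 held 117 and 273. The larger T cell share of the knockout library thus lay in clusters 8 and 10 and not in the CD8-marked cluster. Within cluster 12 alone the cytotoxic median was -0.054, and it was 0.21 and 0.55 in clusters 8 and 10. In clusters 8, 10 and 12 the naive or memory median was 0.17, 0.0197 and 0.34, the regulatory median 0.13, -0.19 and 0.39, and the exhaustion median 0.0029, -0.16 and 0.14, each nearer to 0 than in the whole class, in clusters that such genes help to define. The interferon list had a median of 0.56 in the whole class (percentile 100; 14 of 36 higher, 0 lower), with Ifit1 at 24.3 and 65.2 CPM, and averaged 0.18 within these 3 clusters. The cell cycle list had a median of -0.45 (percentile 0; 0 of 26 higher, 11 lower), with Mki67 at 185 and 112 CPM, but cluster 10 went the other way (0.29; 8 of 26 higher, 0 lower) from clusters 8 (-0.34) and 12 (-0.30). UMIs of other cell types differed in the T cell-like cells too: tumour markers were at 242 and 130 CPM and neutrophil markers at 194 and 121 CPM. NK cell markers were at 2239 and 1128 CPM, but several, such as Gzma and Xcl1, are also in the cytotoxic list. They need not come from other cells. The epithelial list had a median of -1.03 (percentile 0; 0 of 9 higher, 6 lower; -2.19 in cluster 12) and the suppressive neutrophil list -0.20 (2 of 22 higher, 10 lower).

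Shares of T cell-like cells with a UMI were compared for single genes. A Cd4 UMI was found in 21.3% of control and 38.8% of knockout cells (2.91% and 4.71% thinned to 500 UMIs) and a Cd8a UMI in 33.9% and 22.1% (9.05% and 4.61%). Foxp3 was seen in 15.3% and 24.0% (4.85% and 6.41%), Pdcd1 in 50.9% and 34.7% (11.8% and 7.31%), Gzmb in 38.8% and 27.7% (15.5% and 8.02%) and Ifng in 29.6% and 25.6% (7.11% and 4.61%). Trdc, the constant gene of the gamma-delta receptor, was seen in 21.6% and 5.91% (12.8% and 2.30%), and Il17a in 13.1% and 1.20% (6.79% and 0.701%). Cd3e was seen in 81.6% and 80.3% (19.1% and 18.8%). In tumour cells, at median depths of 35924.5 and 40796.5 UMIs, none of these genes exceeded 1.66%, or 0.0784% thinned. Median depths of the T cell-like cells were 6182 and 6499 UMIs. The thinned intervals of Cd4 (1.73 to 4.56 and 3.48 to 6.21), Foxp3 (3.29 to 6.85 and 4.97 to 8.12) and Ifng (5.21 to 9.43 and 3.39 to 6.10) overlap.

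The genes lowest in knockout T cell-like cells were led by Cd163l1 (217 and 14.1 CPM, -3.94, -4.23 to -3.66) and Il17a (186 and 13.9 CPM, -3.74, -4.03 to -3.46), with Cdh10, Prickle2 and Il1r1 (93.2 and 14.8 CPM). Cd163l1, Il17a and Prickle2 are leading genes of cluster 20, which also expresses Trdc and held 121 control and 22 knockout cells. Gzmd, Gzmf, Gzme, Abi3bp and Ppp1r14c completed the 10. The highest were the type 2 cytokine genes Il5 and Il13, with Il3, Hs3st1, Mcpt1, Mcpt2, Il17rb, Kcnc2, Pde7b and Rab27b. Il13 was at 5.78 and 94.1 CPM (4.03), from 5 control and 21 knockout cells with 38.8% of the UMIs in 1 cell. Il5 had 96 UMIs in 10 knockout cells, 47.9% of them in 1 cell, and none in the control (18.8-fold higher against 3 control counts, exact log2 bound 3.90). With the stricter cell filter its log2 value was -0.026. A control without UMIs is set against 3 counts, so that value gives no direction. It does show that the Il5 difference of the main filter was lost with the stricter one. Mcpt1 and Mcpt2 are mast cell protease genes that lead the mast or basophil-like cluster, and over 25% of the UMIs sat in 1 cell for 9 of the 20 genes.

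In monocyte-like cells (278 control, 637 knockout, all in cluster 7 led by Plcb1 and Ly6c2) interferon genes were again higher in the knockout. The list had a median of 0.34 (percentile 100; 8 of 36 higher, 0 lower), with Iigp1, an immunity-related GTPase gene, at 79.5 and 229 CPM (1.53, 1.31 to 1.74), Gbp4 at 95.8 and 192 CPM and Cxcl9 at 445 and 874 CPM. Ifit3 (46.5 and 33.0 CPM) and Oas1a (89.6 and 60.2 CPM) were lower by less than 1.5-fold. The MHC class II list had a median of 0.27 (percentile 99.95), with Ciita at 72.9 and 129 CPM. Cd274 was at 255 and 434 CPM (0.77), Ccl2 at 283 and 491 CPM, Ccl7 at 105 and 245 CPM and Ccl5 at 330 and 673 CPM. The alternatively activated list was lower (median -0.43, percentile 0; 3 of 21 higher, 8 lower), with Arg1, which depletes arginine, at 1197 and 747 CPM (-0.68, -0.74 to -0.62) and Spp1, osteopontin, at 558 and 269 CPM, whereas Mrc1 was at 468 and 656 CPM, a direction that turned when doublets were kept. Retnla was lowest of the ranked genes (638 and 64.8 CPM), with 70.0% of its UMIs in 1 cell. The lectin-like receptor gene Olr1 was at 85.7 and 36.1 CPM.

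Neutrophil-like cells (558 control, 271 knockout, all in cluster 11) had the largest interferon difference of the 8 classes compared. At resolution 2.0 they split into a cluster led by G0s2 (236 control, 262 knockout) and another led by S100a8 (322 control, 9 knockout). Lists were not compared within these, so the class values below can reflect a different mix of neutrophil states. The list had a median of 1.14 (percentile 100; 27 of 35 higher, 0 lower), with Gbp4 at 16.5 and 110 CPM (2.74, 2.08 to 3.46), and Cxcl10 at 72.9 and 678 CPM, 22.3% of it in 1 cell. MHC class I genes were also higher (median 0.97, percentile 100; 17 of 20 higher, 0 lower), with Tap1, a peptide transporter gene, at 102 and 244 CPM and B2m at 1492 and 2380 CPM. Hypoxia and glycolysis genes were lower (median -1.26, percentile 0; 0 of 24 higher, 19 lower): Ero1l, an endoplasmic reticulum oxidase gene induced by hypoxia, was at 797 and 103 CPM (-2.96, -3.30 to -2.63), and Bnip3 at 335 and 63.5 CPM. In the suppressive neutrophil list (median -0.13, percentile 5.71; 4 of 25 higher, 7 lower) Hilpda was at 874 and 164 CPM and Ptgs2, the gene of cyclooxygenase 2, at 1147 and 2705 CPM. These cells had median depths of 2482.5 and 2725 UMIs, and their UMIs of monocyte markers were at 467 and 974 CPM, which moved with the interferon and MHC genes. UMIs of tumour markers were at 869 and 637 CPM and the epithelial list had a median of -1.56 (1 of 7 higher, 6 lower), which moved with the hypoxia genes. Genes of the unfolded protein response were lower too (median -0.60; 0 of 12 higher, 6 lower), mitochondrial transcripts were higher (0.46), and of the dissociation list 8 of 17 were higher and 6 lower, with Hspa1a at 144 and 11.4 CPM and Hspa1b at 102 and 6.35 CPM.

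NK cell-like cells numbered 136 in the control and 497 in the knockout, all in cluster 4, led by Gzma, Xcl1 and Ncr1. Mki67 was at 166 and 98.0 CPM (-0.76, -1.02 to -0.49), with 24.0% of its UMIs in 1 cell. Gzmb was at 703 and 853 CPM (0.28, 0.16 to 0.40) and Ifng at 164 and 166 CPM. The cytotoxic list, which shares several genes with the markers that named the cluster, had a median of 0.17 (percentile 99.95; 4 of 24 higher, 0 lower), and its highest members Gzmf, Gzme and Gzmd had 63.9%, 47.1% and 59.8% of their UMIs in 1 cell. The interferon list had a median of -0.18 (percentile 0.51; 1 of 34 higher, 3 lower).

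**Figure D3:**
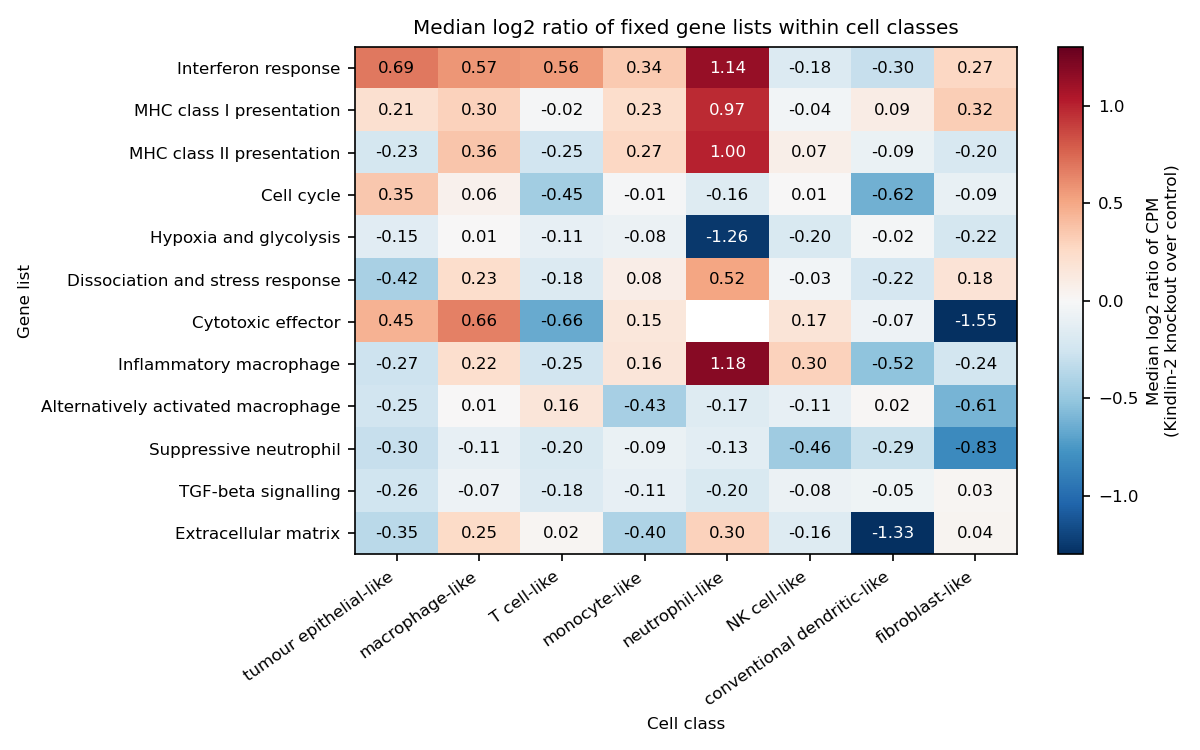
Median log2 ratio of CPM (knockout over control) of 12 fixed gene lists (vertical axis) in 8 cell classes (horizontal axis), from blue (lower) to red (higher), with the value in each cell and an empty cell where too few genes were measured. The interferon list is highest in neutrophil-like cells at 1.14 and lowest in conventional dendritic-like cells at -0.30.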

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

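The comparisons within clusters, in the CD8-marked cluster alone, with monocyte-like cells counted as macrophages and for the shares of mast, B and pericyte cells were chosen after the results were seen, and all other alternatives were fixed before. No paired analysis was possible because each group has 1 library, both numbered replicate 1, and for the same reason no library could be left out. Of 85 comparisons of cell shares with an alternative, 74 stayed within their counting interval, as did 1130 of 1370 for single genes. Of 801 for gene lists, 760 stayed within the bootstrap interval over the list members. For the tumour ranking, 17 and 16 of the 20 genes stayed with minimums of 20 and 200 UMIs, for the macrophage ranking 9 and 8. Over all classes, 6 of 16 ranking comparisons were counted as unchanged and 10 as moved, because too few genes were shared. With 200 UMIs 7 classes moved and 1 did not, and with 20 UMIs 3 moved and 5 did not. Most rankings outside the tumour cells thus depend on the gene minimum. No scaling moved the median of all genes in a class by over 0.1. Depth limits the small classes: in NK cells the interval excluded 0 for 53.8% of simulated 1.5-fold changes, and counting intervals are too narrow for genes held by few cells.

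Among immune cells only, the log2 share ratios moved to -0.79 (macrophage-like), 0.44 (T), 1.62 (NK), 0.95 (monocyte-like), -1.29 (neutrophil-like) and 0.91 (conventional dendritic-like), because tumour cells left the total. At resolution 2.0 the tumour share ratio was -0.44, and at resolution 0.5 the endothelial-like ratio reversed to 0.20. With monocyte-like cells counted among them, the macrophage-like ratio reversed to 0.066, and with the stricter filter the mast or basophil-like ratio was 1.15. Median-ratio scaling gave -1.66 for Fermt2 in tumour cells. Unthinned, the ratio of T cells with a Gzmb UMI was -0.49.

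With every cell weighted equally, the tumour interferon median was 0.83 and the regulatory list median in T cells 0.18. The cell cycle list in conventional dendritic-like cells reversed to 0.089, as did Cd274 (-0.00102) and Vim (0.049) in macrophage-like cells and S100a9 in monocyte-like cells (-0.32). Averaged over clusters, the tumour interferon median was 0.46, and the cell cycle median of tumour cells reversed to -0.11 and the hypoxia median moved to 0.058, although some clusters are led by cycle genes themselves. The dissociation median of tumour cells became -0.28. In T cells the naive and regulatory medians became 0.18 and 0.11, and the cytotoxic median reversed to 0.24. In the CD8-marked cluster alone the cytotoxic median was -0.054.

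The stricter cell filter reversed Ctsk in macrophage-like cells (0.22), Rnase2a, S100a9 and Tgfb1 in monocyte-like cells (0.40, -0.10 and 0.067), and Arg1 and Ccl2 in conventional dendritic-like cells (-0.72 and -0.79). Il5 in T cells went to -0.026 and was counted as reversed. It had no control UMI under the main filter, and such a ratio is a bound against 3 counts that gives no direction. The higher Il5 of the main filter was thus lost with the stricter one. Keeping doublets reversed Vim in macrophage-like cells (0.17), S100a8 in T cells (0.042), and Ccl17, Csf1 and Mrc1 in monocyte-like cells (-0.31, -0.51 and -0.031). It also reversed Cxcl1 in neutrophil-like cells (-0.55), Spp1 in NK cells (-0.079) and S100a9 in fibroblast-like cells (-3.05). Where no reason is given, the cause was not tested.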

Other observations

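The tests of the cell shares, of the cluster mix and immune RNA behind the interferon list, of a library-wide offset and of whole chromosomes were chosen after the results were seen, and the others before.

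Fibroblast-like cells (109 control, 101 knockout) differed in genes of the contractile state and in lists of other cell types. The myofibroblastic list had a median log2 ratio of -0.56 (0 of 17 members at least 1.5-fold higher, 8 lower), with Lrrc15, a marker of myofibroblasts in tumours, at 327 and 168 CPM, and Myl9, a myosin light chain gene, at 157 and 71.5 CPM. The inflammatory fibroblast list had a median of 0.15 (7 of 19 higher, 1 lower), with Cxcl12, a chemokine gene for lymphocytes, at 241 and 509 CPM and the hyaluronan synthase gene Has1 at 115 and 243 CPM. MHC class I genes had a median of 0.32 and interferon genes 0.27. Lists of other cells moved as much or more: cytotoxic -1.55 (2 of 11 higher, 9 lower), suppressive neutrophil -0.83 (2 of 19 higher, 11 lower), alternatively activated macrophage -0.61 (0 of 13 higher, 7 lower) and epithelial 0.42 (5 of 11 higher, 2 lower), with T cell markers at 90.5 and 38.2 CPM. Over 25% of the UMIs sat in 1 cell for 16 of the 20 genes ranked in this class.

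Conventional dendritic-like cells (149 control, 333 knockout) went the other way from most classes in the interferon list, with a median of -0.30 (0 of 36 higher, 10 lower). Rsad2 was at 140 and 32.4 CPM (-2.10, -2.39 to -1.82) and Ifit2 at 86.7 and 39.2 CPM. The cell cycle list had a median of -0.62 (0 of 26 higher, 13 lower), a direction that turned with every cell weighted equally. MHC class II genes were close (median -0.09), with H2-Eb1 at 4682 and 4175 CPM. UMIs of tumour markers in these cells were at 653 and 205 CPM. Cluster 15 (Wdfy4, Naaa, Cd209a) held most of the class in both libraries, and cluster 13 (Ccl22, Ccr7) the rest.

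More NK, T, monocyte and dendritic cells and fewer neutrophils were found in the knockout library, and fewer macrophages unless the monocyte-like cells are counted with them (log2 ratio 0.066, -0.031 to 0.16). Fewer tumour cells in the suspension would raise all immune classes alike, yet among immune cells the NK and neutrophil ratios lay 2.91 apart on the log2 scale. Shallow cells passing the filter would lower the NK ratio when the filter is tightened, and it was 2.02 (1.74 to 2.31). NK cell-like cells were deep, with medians of 6101.5 and 6470 UMIs, and the stricter filter held 134 and 484 against 136 and 497. Their ratio could therefore hardly move and does not decide the question. Over the classes, 12 share ratios stayed within their counting interval with that filter and 1, of mast or basophil-like cells, moved. A difference between individual tumours or suspensions cannot be told apart from the knockout with 1 library per group. A role of tumour Kindlin-2 in these shares may be proposed only as a hypothesis. Lower Ccl2 in the tumour cells goes with a larger share of monocyte-like cells, not a smaller one. However, Ccl2 was higher in knockout macrophage-like (162 and 213 CPM), monocyte-like (283 and 491 CPM) and fibroblast-like cells (534 and 803 CPM). In conventional dendritic-like cells its direction turned with the stricter cell filter.

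The interferon list was higher in knockout tumour cells. A different mix of tumour clusters could account for part, cluster 0 being itself led by Ifit3. The class median of 0.69 became 0.46 (0.34 to 0.59 over list members) when clusters were averaged. The mix of these clusters thus did not account for all of it. An earlier bound, over 0.3 in every cluster, had not been met, the lowest being 0.23. A mix of finer states was not tested. At resolution 2.0 a tumour cluster led by Ifit3 and Ifit1 held 88 control and 176 knockout cells. RNA of immune cells in the droplets, taken off the knockout levels for 9 immune classes at the share their markers in the tumour cells allow, left the median at 0.67 (0.44 to 0.75), a test that replaced an earlier attempt with macrophage and neutrophil markers alone. A library-wide offset would reach every class, whereas the lowest class stood at -0.30. A response to interferon from the larger T and NK compartment, whose Ifng per class was close between the libraries, and a property of the knockout line both stay open and were not tested.

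In the tumour cells 12 genes on 9 chromosomes were at least 16-fold apart, among them Pitx1, Rab6b, Cldn7, Nox4, Ccl2 and Rnase4 on the control side and Csn3, Dennd2a and Cyp7b1 on the knockout side. A different mix of clusters would remove such gaps within clusters, yet 91.7% of the genes stayed at least 4-fold apart in every cluster, the exception being the haemoglobin gene Hbb-bs. UMIs of erythroid markers, Hbb-bs among them, were lower in the knockout in every class compared. They were at 22.8 and 1.34 CPM in tumour cells and 25.8 and 1.23 CPM in NK cell-like cells. Hbb-bs therefore need not mark a difference of the tumour cells themselves. Csn3 was seen in 38 control and 304 knockout tumour cells, with 18.5% of its UMIs in 1 cell. With the stricter cell filter it was also a leading gene of the unnamed luminal mammary gland cluster (43 control, 77 knockout cells). Whether gland cells were a source of Csn3 was not tested. Gain or loss of the region around each gene would shift its neighbours, whose signed median pooled over the 12 genes was 0.025 (-0.051 to 0.14). A pooled median does not decide for single genes, whose neighbour medians ran from -0.33 (Hbb-bs) to 0.32 (Rab6b). Those shifts were far smaller than the gaps of the genes themselves. Unequal copy number of whole chromosomes would shift the other genes there by about as much, yet the largest chromosome median in the direction of its gene was 0.12 (0.099 to 0.15). That test replaced bounds of 0.15 and 0.3 on any chromosome, and its own bound was set after the medians had been seen. It shows only that whole chromosomes shifted far less than 16-fold. Smaller shifts were seen on chromosomes 2 (-0.22), 16 (-0.22), 19 (0.21) and 18 (0.154), with macrophages within 0.03. Each of these lay beyond the replaced bound of 0.15. Parts of chromosomes 9 (-0.20 to -0.29), 11 (-0.22), 15 (0.32 and -0.21), 12 (0.42), 6 (0.40) and 13 (0.68, where 31 of 50 genes are histone genes) shifted too, with macrophages within 0.05. Separate histories of the cell lines, for example of clones, may therefore add to the knockout itself, and these libraries hold no second line of either kind to compare.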
